A study of Mus musculus with 11 samples.

How the data were processed

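RNA labelled for a few minutes with the uridine analogue 4-thiouridine (4-sU) was purified and sequenced, so that the reads come mainly from transcripts made during the labelling. The cells were mouse embryonic stem (ES) cells of the lines RT7 and RT10, which carry a tamoxifen-inducible Cre recombinase at the Rosa26 locus and floxed alleles of Taf7 (RT7) or Taf10 (RT10). Per the labels' protocols, cells received ethanol (vehicle) or 4-hydroxytamoxifen (4-OHT) until day 3 and were labelled with 500 µM 4-sU. The labels state the labelling time as 5 minutes in one place and 15 minutes in another, so it is left open here. Per the labels' protocols, 25 µg of labelled RNA of Drosophila S2 cells and 25 µg of unlabelled yeast RNA were added per 200 µg of mouse RNA before purification, and libraries were made with a strand-marking, ribosomal RNA-depleting total RNA kit.

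The deposited count tables hold whole-number counts per gene for 34444 mouse and 17737 Drosophila genes in 11 libraries. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 1.10, Bowtie2 2.2.8, STAR 2.5.3a, HTSeq, DESeq2 1.16.1 and the builds mm10 and BDGP6. How reads were assigned to features and whether strand was used in counting are not given in the sources used here, so genes that overlap or lie antisense to another cannot be separated with certainty. A combined table deposited by the authors repeats the mouse counts, gives counts divided by a size factor, and gives the authors' log2 fold changes, p-values and adjusted p-values for each line. From the values, the authors' size factors equal the median-of-ratios size factors of the Drosophila counts, with a largest relative gap of 1.55e-15. The 11 columns of counts divided by transcript length were not used. The combined table leaves out 1260 mouse genes, all with 0 counts. Gene names, biotypes and mm10 coordinates come from that table, and 34412 of the mouse identifiers were found in GENCODE M21, which uses the same assembly. No row named no gene.

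Groups were taken from the sample titles: RT7 vehicle (3 libraries), RT7 4-OHT (3), RT10 vehicle (3) and RT10 4-OHT (2). Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples. No pair of libraries within a group agreed within sampling noise, with chi-square per degree of freedom of 13.1 to 49.9 over genes with at least 20 counts in the pair. Mouse gene counts were tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, 2-sided) in R 4.3.3, with all 11 libraries in 4 groups sharing the estimate of spread. Library sizes were set by the median-of-ratios size factors of the Drosophila counts, called the spike-in scale here. Genes were kept by filterByExpr, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every adjusted p of a gene is from this test unless another is named, and standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. On the spike-in scale the gene-wise spread shrank fully to its trend (prior degrees of freedom without limit, against 8.39 on the TMM scale), and the common dispersion was 0.0855 against 0.0305 with TMM factors of the mouse counts. Library-wide differences of mouse RNA relative to the spike-in thus made up much of the modelled spread. Whether the spike-in or the labelled mouse RNA was their source cannot be told from these values. With this shrinkage the SE and p of most genes rest on the trend and not on the gene's own spread. They can be too small for genes that vary more than the trend. Chac1 in RT10 had 305 ± 221 scaled counts with vehicle (mean ± SD, n = 3). Its edgeR adjusted p was 2.95e-09 on the spike-in scale and 0.0293 with TMM factors.

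The named genes were chosen by a rule fixed before the data were examined, together with the tests, the gene lists and most of the other settings tried. The rule took Taf7 and Taf10. For each line it took the 10 genes with the largest fold change in each direction that passed the threshold on the spike-in scale and, with the same sign, with TMM factors. They also needed a mean of at least 50 counts and no overlap between vehicle and 4-OHT libraries. Predicted gene models and pseudogenes were left out. The rule took 5 genes per direction for the other comparisons, the 5 with the smallest p where none passed, and up to 4 members per gene list with the smallest p. A total of 33 gene lists were tested with camera of limma 3.58.1 against all other genes, with a preset inter-gene correlation of 0.01 and again with an estimated one, for lists of at least 5 tested genes. The ratio of mouse to Drosophila counts per library was compared with exact permutation tests.

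Alternatives were TMM and DESeq2 size factors of the mouse counts, TMM factors or totals of the Drosophila counts, no filter, a mean of at least 50 counts, only the groups compared, the replicate number as a block, each library left out in turn, DESeq2 1.42.0 and a test against a fold change of 1.5. Whether equal replicate numbers mark paired samples was checked from the correlation of the libraries' deviations from their group means. In RT7 the same-number correlations were 0.39, 0.52 and 0.45, so the numbers were taken as pairs. In RT10 they were 0.06 and -0.46, so there they were not. Unlike numbers correlated at 0.46 (vehicle 2 with 4-OHT 1) and 0.49 (vehicle 3 with 4-OHT 2). The library identifiers in the labels run in order, with a gap between RT10 vehicle 3 and RT10 4-OHT 1. A missing first 4-OHT library would shift the numbers in the way these correlations do, but the labels do not say so. A shifted pairing in RT10 is therefore likely enough to distrust its numbers as pairs. It was not fitted, and 2 treated libraries, whose deviations mirror each other, cannot settle it by correlation alone. Between the vehicle libraries of the lines same-number correlations were 0.07, 0.36 and 0.37, and the highest unlike-number one was 0.0032. A batch shared across the lines by number is thus possible too, and the main tests have no block.

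The tests were tried on simulated counts with the real means, library sizes and dispersions of the spike-in scale and 200 changed genes. For RT7, 95.5% of the genes changed 4-fold and 25.4% of those changed 2-fold were recovered over 18157 genes, with 4 false calls among 84. For RT10, 93.9% and 25.4% were recovered over 18198 genes, with 7 false calls among 88. For the difference of the effects, 59.1% of 4-fold and 2.99% of 2-fold changes were recovered over 18173 genes, with 1 false call among 42. For the vehicle comparison, 93.9% and 19.4% were recovered over 18174 genes, with 1 false call among 79. A simulated list of 30 genes changed 1.5-fold was called with the preset correlation in each of the 4 comparisons. The simulated genes were drawn independently, while the estimated correlation within the real lists was 0.16 to 0.86. Variation shared by the genes of a library was thus absent, and a split of the RT7 libraries that mixed treatments called 5815 genes. The rates of false gene calls and false list calls in the real data were therefore not measured by these simulations.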

Results

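Nascent RNA was profiled in 11 libraries of mouse ES cells in which 4-OHT activates Cre to delete Taf7 (line RT7) or Taf10 (line RT10), which encode subunits of TFIID, the general transcription factor that binds core promoters. TAF10 is also a subunit of the coactivator complex SAGA. The design asks how newly made RNA changes when either subunit is lost. Mouse counts per library ran from 25987282 to 31090597 in RT7 and from 15845760 to 17963955 in RT10, and Drosophila spike-in counts from 6466288 to 12562394 over all libraries. Counts overlapping ribosomal RNA at Gm26917 and Gm42418 made up 8.01% to 17.6% of mouse counts.

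Taf7 (ENSMUSG00000051316, mm10 chromosome 18, 37640491 to 37644204) fell in RT7 after 4-OHT, from 1610 ± 558 to 441 ± 93.5 spike-in-scaled counts (mean ± SD, n = 3 and 3). The log2 fold change was -1.87 ± 0.30 (SE; edgeR adjusted p = 2.13e-06), and each treated library lay below each vehicle library. Raw counts were 1397, 1657 and 1425 with vehicle and 325, 496 and 388 with 4-OHT. In RT10 Taf7 had a log2 fold change of -0.27 ± 0.33 (edgeR adjusted p = 0.862). Taf10 (ENSMUSG00000043866, mm10 chromosome 7, 105739393 to 105744361) was not lower in the libraries labelled RT10 4-OHT. Its raw counts were 196, 268 and 238 with vehicle and 345 and 294 with 4-OHT, and its log2 fold change was 0.15 ± 0.37 (edgeR adjusted p = 0.943). A count over a whole gene need not fall when part of the gene is deleted, so Taf10 counts do not check the labels of RT10. In RT7 Taf10 had a log2 fold change of 0.19 ± 0.33 (edgeR adjusted p = 0.906).

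**Figure D1:**
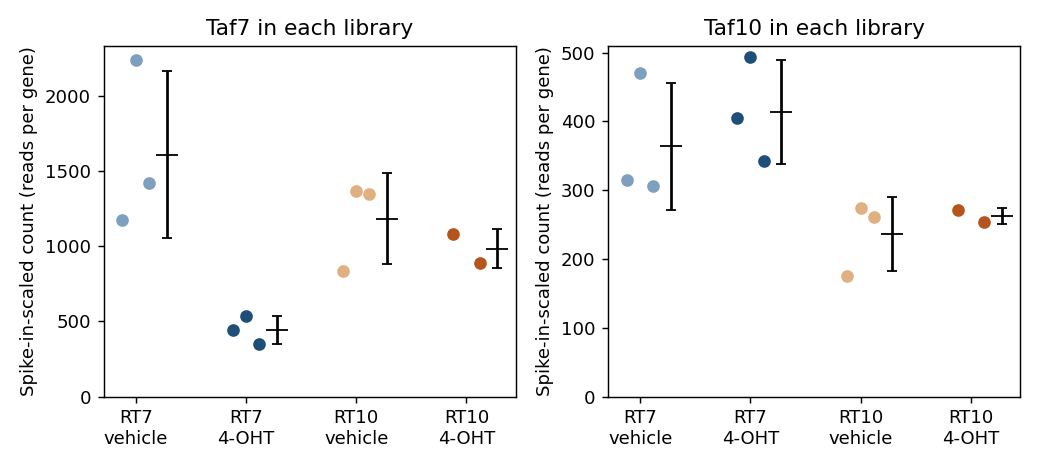
Spike-in-scaled counts of Taf7 (left) and Taf10 (right) in each library, by line and treatment. Points are libraries and bars show the mean ± SD; Taf7 lies lower in the 3 RT7 4-OHT libraries than in the 3 RT7 vehicle libraries, while Taf10 shows no such gap in RT10.

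The total of labelled mouse RNA relative to the spike-in was compared first. In RT7 the ratio of mouse to Drosophila counts was 3.49 ± 0.693 with vehicle and 3.56 ± 0.664 with 4-OHT (SD, n = 3 and 3), and the exact permutation p of the log2 difference of 0.03 was 1. In RT10 it was 1.75 ± 0.319 with vehicle and 1.44 ± 0.0327 with 4-OHT (SD, n = 3 and 2), a log2 difference of -0.27 with an exact permutation p of 0.4. Both tests were 2-sided. The RT7 design cannot give a p under 0.1, and the smallest possible p is higher in RT10, which has fewer libraries.

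**Figure D2:**
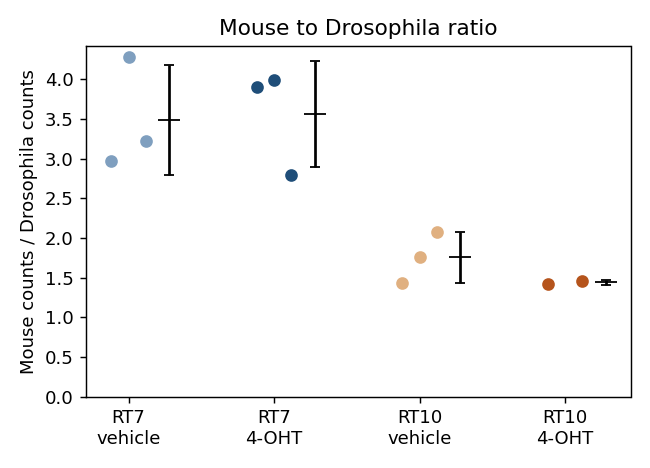
Ratio of mouse to Drosophila counts in each library, by line and treatment, with the mean ± SD beside the points. The RT7 libraries spread from 2.80 to 4.28 and the RT10 libraries from 1.42 to 2.07.

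The deletion of Taf7 was examined first, in RT7. Among the genes named by the fixed rule, Slc7a11, the cystine and glutamate antiporter (mm10 chromosome 3, 49892526 to 50443614), fell by 2.32 on the log2 scale (SE 0.40, edgeR adjusted p = 1.90e-05). Pck2, mitochondrial phosphoenolpyruvate carboxykinase, had a log2 fold change of -1.86 ± 0.34, and Nupr1, a stress-induced chromatin protein, one of -2.06 ± 0.40. The lincRNA Platr3 (-2.17 ± 0.33), the lipoprotein receptor gene Vldlr (-2.09 ± 0.38), the fatty acid elongase gene Elovl2 (-1.79 ± 0.36), the nucleoside transporter gene Slc28a3 (-1.79 ± 0.42), the serotonin receptor gene Htr5a (-1.86 ± 0.38) and Galnt9 (-1.80 ± 0.41) also fell. Genes that rose were led by the ammonium transporter gene Rhcg (log2 fold change 2.51 ± 0.39, edgeR adjusted p = 5.81e-07) and the ubiquitin ligase gene Trim17 (2.06 ± 0.33). Mobp (1.94 ± 0.37), Mafa (1.80 ± 0.47), Tcta (1.72 ± 0.36), the glycogen branching enzyme gene Gbe1 (1.61 ± 0.30), the quinone reductase gene Nqo1 (1.53 ± 0.29), AC127341.3 (1.44 ± 0.36), Rgs6 (1.40 ± 0.34) and Caprin2 (1.37 ± 0.29) rose as well. The errors are SE, and these genes passed an edgeR adjusted p of 0.05. The authors' deposited table does not call Nupr1 (authors' adjusted p 0.229) or Htr5a (0.124) in RT7 and calls the others named here.

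Of 18674 genes tested in RT7, 54 rose and 148 fell, 1789 had an unadjusted p under 0.05, and the median log2 fold change was 0.01. With the replicate number as a block in RT7 alone, chosen after seeing the data, 145 rose and 498 fell. With a block in both lines 105 rose and 342 fell, and with TMM factors of the mouse counts 450 rose and 833 fell. The SE and p-values given for RT7 genes are from the test with no block. Left out in turn, RT7 4-OHT 1 reduced the 202 calls to 33, and RT7 4-OHT 3 to 124 (81 higher and 43 lower). Without RT7 vehicle 2 there were 277 calls, of which 208 were higher and 69 lower, so the excess of lower calls in RT7 depends on single libraries on the spike-in scale. With TMM factors more genes fell than rose without any 1 of the 6 RT7 libraries, from 137 higher and 318 lower without RT7 4-OHT 1 to 437 and 809 without RT7 4-OHT 2. Of the 19 named genes of largest fold besides Taf7, the calls of AC127341.3, Caprin2, Galnt9, Mafa, Nupr1, Pck2, Rgs6, Slc28a3 and Tcta were lost without RT7 4-OHT 1. Some of these were also lost without RT7 4-OHT 2 (AC127341.3, Mafa, Rgs6), RT7 4-OHT 3 (Galnt9, Slc28a3), RT7 vehicle 1 (AC127341.3, Mafa) or RT7 vehicle 3 (AC127341.3, Mafa, Rgs6, Tcta). The authors' deposited table lists 134 changed genes in RT7, of which 113 were also called here.

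Genes of the integrated stress response, the program driven by ATF4 when translation initiation is limited, lay lower than other genes in RT7 with a preset correlation (adjusted p = 0.900 with an estimated correlation, and 0.186 with one on the TMM scale). Of 31 tested members 8 fell and 0 rose (13 fell adjusted over the list alone), with a median log2 fold change of -0.65. With TMM factors 15 fell and 0 rose. Chac1, which degrades glutathione, had a log2 fold change of -2.12 ± 0.38 (SE; edgeR adjusted p = 1.20e-04, and 0.0626 with TMM factors). Of 81 ribosomal protein genes 4 fell and 0 rose (11 fell adjusted over the list alone), with a median of -0.49. With TMM factors 36 of them fell and 0 rose. This list too was called lower with a preset correlation, but its adjusted p = 0.900 with an estimated correlation, and 0.309 with one on the TMM scale. Those that fell on the spike-in scale were Rpl22l1 (-1.33 ± 0.29), Rplp1 (-1.18 ± 0.29), Rpl23a (-1.20 ± 0.30) and Rpl10 (-1.03 ± 0.29). All 4 calls were lost without RT7 4-OHT 1, some also without RT7 vehicle 2 (Rpl10), vehicle 3 or 4-OHT 3 (Rpl23a, Rpl10). The call of Chac1 was lost without RT7 4-OHT 3. Among primitive endoderm markers 1 of 16 fell, the collagen gene Col4a2 (-1.17 ± 0.33), with a median of -0.57 and adjusted p = 0.900 with an estimated correlation. The call of Col4a2 was lost without RT7 vehicle 2, 4-OHT 1 or 4-OHT 3.

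The other 10 lists called in RT7 lay higher than other genes with a preset correlation, and each of them had adjusted p = 0.900 with an estimated correlation. Of 15 TFIID subunit genes Taf4b rose (log2 fold change 1.21 ± 0.28, SE; edgeR adjusted p = 0.00447) and Taf7 fell, with a median of 0.47 (adjusted p = 0.900 with an estimated correlation). On the TMM scale 7 rose and 1 fell (adjusted p = 0.136 with an estimated correlation). Of 29 genes of RNA polymerase II subunits and general factors, the TFIIA gene Gtf2a1 rose (1.01 ± 0.28) and 0 fell, with a median of 0.34 (adjusted p = 0.900 with an estimated correlation). With TMM factors 8 of the 29 rose and 0 fell. Mediator subunits (31 tested, median 0.33) and mitochondrially encoded genes (9 tested, median 0.50) had 0 members past the threshold on the spike-in scale and adjusted p = 0.900 with an estimated correlation. With TMM factors 5 Mediator subunits rose and 0 fell, and 0 mitochondrially encoded genes passed. The remaining lists, with the same adjusted p = 0.900 with an estimated correlation, were TBP and TAF paralogs (13 tested, median 0.32, Taf4b past the threshold), replication-dependent histones (56 tested, median 0.15, Hist1h2bc past the threshold) and, with 0 members past it, ribosome biogenesis (0.18), mitosis (0.17), the two-cell-like state (0.41) and nuclear-encoded oxidative phosphorylation (0.18). The call of the two-cell-like state was lost with TMM factors and without RT7 vehicle 1, RT7 4-OHT 2 or RT7 4-OHT 3, that of mitosis without RT7 vehicle 1 or RT7 4-OHT 2, that of oxidative phosphorylation without RT7 vehicle 2 or RT7 4-OHT 2, and that of histones without RT7 vehicle 3. The calls of Taf4b, Gtf2a1 and Hist1h2bc were lost without RT7 vehicle 3 or RT7 4-OHT 1, those of Gtf2a1 and Hist1h2bc also without RT7 vehicle 1, and that of Gtf2a1 without RT7 4-OHT 2. None of the 13 calls among 33 lists held with an estimated correlation. The shared 0.900 comes from the adjustment, since their unadjusted camera p ran from 0.0810 (integrated stress response) to 0.687 (oxidative phosphorylation). The estimated correlations of these lists were 0.479 to 0.853, so a lost call does not show that a list was unchanged. The mitochondrial share of mouse counts was 0.780% ± 0.139 with vehicle and 1.05% ± 0.164 with 4-OHT (SD, n = 3 and 3).

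In RT10, the genes named by the fixed rule included members of the integrated stress response that were also lower in RT7. Chac1 had a log2 fold change of -3.80 ± 0.50 (SE; edgeR adjusted p = 2.95e-09), Nupr1 of -3.65 ± 0.52 and Slc7a11 of -2.96 ± 0.49. The transcription factor gene Atf3 had one of -3.19 ± 0.45. With TMM factors the edgeR adjusted p of Chac1, Nupr1 and Atf3 were 0.0293, 0.0253 and 0.0333, and that of Slc7a11 was 0.00211. The authors' deposited adjusted p in RT10 were 0.0144, 0.0258, 0.0356 and 1.59e-05 in that order. In RT7 the authors' table calls Slc7a11 (3.68e-04) but not Chac1 (0.209), Nupr1 (0.229) or Atf3 (0.456). Ccnb1ip1, which encodes a meiotic crossover regulator (mm10 chromosome 14, 50789248 to 50807732), fell from 4069 ± 1512 to 439 ± 25.7 spike-in-scaled counts (mean ± SD, n = 3 and 2). Its log2 fold change was -3.21 ± 0.37. The antisense transcript Ptprtos (-4.37 ± 0.45), Htr5a (-3.30 ± 0.50), the elastic fibre gene Fbln5 (-3.05 ± 0.50), Mir142hg (-2.89 ± 0.42) and BC048559 (-2.73 ± 0.43) fell as well. Trim17 (2.32 ± 0.35), the dynein gene Dnah9 (2.28 ± 0.53), BC051019 (2.16 ± 0.42), Sned1 (1.68 ± 0.40), the histone gene Hist1h2bc (1.68 ± 0.31) and Usp17lb (1.48 ± 0.44) rose. AC127341.3 (1.46 ± 0.40), Rgs6 (1.39 ± 0.36), Gtf2a1 (1.36 ± 0.31) and the TFIID gene Taf6 (1.32 ± 0.40) rose too. Usp17lb belongs to a family of near-identical copies and histone genes share sequence, so their counts are uncertain. In RT10 the authors' deposited table does not call Fbln5 (authors' adjusted p 0.0606) or Usp17lb (0.614) and calls the others named here.

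Of 18674 genes tested in RT10, 38 rose and 327 fell, 2293 had an unadjusted p under 0.05, and the median log2 fold change was -0.21. With TMM factors of the mouse counts the median was 0.03 and 582 genes rose and 604 fell, so that 49.1% of calls were higher against 10.4% on the spike-in scale. Left out in turn, RT10 4-OHT 2 reduced the 365 calls to 14, RT10 4-OHT 1 to 108 and RT10 vehicle 2 to 122. Of the 20 named genes of largest fold, the calls of AC127341.3, BC051019, Dnah9, Fbln5, Gtf2a1, Hist1h2bc, Htr5a, Rgs6, Slc7a11, Sned1, Taf6 and Usp17lb were lost without RT10 4-OHT 2. Of these, AC127341.3, Rgs6, Taf6 and Usp17lb were also lost without RT10 4-OHT 1, vehicle 1 or vehicle 2, Sned1 without vehicle 1, Dnah9 without vehicle 2 and Taf6 without vehicle 3. The authors' deposited table lists 301 changed genes in RT10, of which 251 were also called here.

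Of the 31 integrated stress response genes, 14 fell and 0 rose in RT10 (24 fell adjusted over the list alone), with a median log2 fold change of -1.09, which was -0.89 relative to all genes. With TMM factors 19 fell and 0 rose. The list, called lower with a preset correlation, had adjusted p = 0.953 with an estimated correlation and 0.186 with one on the TMM scale. The serine synthesis gene Psat1 had a log2 fold change of -1.96 ± 0.35 (SE; edgeR adjusted p = 9.17e-06). Of 81 ribosomal protein genes 18 fell and 0 rose (55 fell adjusted over the list alone), with a median of -0.79 (-0.59 relative to all genes), among them Rpl22l1 (-2.25 ± 0.35) and Rplp1 (-1.54 ± 0.33). With TMM factors 30 of the 81 fell and 0 rose. With an estimated correlation the adjusted p of the ribosomal protein genes was 0.953, and 0.400 on the TMM scale. In the unfolded protein response list Herpud1 fell (-1.64 ± 0.36), among primitive endoderm markers Dab2 (-1.65 ± 0.46) and among trophectoderm markers Gata3 (-1.67 ± 0.44). The medians of these lists were -0.43, -0.75 and -0.92, and their adjusted p = 0.953 with an estimated correlation. Without RT10 4-OHT 2 the calls of Psat1, Rplp1, Herpud1, Dab2 and Gata3 were lost, and some also without RT10 4-OHT 1 (Rplp1, Dab2, Gata3), vehicle 1 (Dab2) or vehicle 2 (Herpud1, Gata3). The trophectoderm call was lost with TMM factors and without RT10 4-OHT 1 or vehicle 1, and the unfolded protein response call without RT10 4-OHT 2, vehicle 2 or vehicle 3.

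TFIID subunit genes had a median log2 fold change of 0.31 in RT10, which lay 0.52 above the median of all genes (adjusted p = 0.953 with an estimated correlation). Taf6 rose, and Taf5 had a log2 fold change of 1.06 ± 0.33 (SE; edgeR adjusted p = 0.0624). On the TMM scale 7 of 15 rose and 0 fell, and this was the only list call that held with an estimated correlation there (adjusted p = 0.0259). Genes of the two-cell-like state, a rare state of ES cultures marked by the Zscan4 family, had a median of 0.84 over 19 tested genes (adjusted p = 0.953 with an estimated correlation), from a level that was already higher in RT10 vehicle than in RT7 vehicle in 16 of them. Of these 0 passed the threshold and 2 rose adjusted over the list alone; Zscan4d had a log2 fold change of 1.18 ± 0.37 (edgeR adjusted p = 0.0677). Zscan4 copies are near-identical, so their single values are uncertain. Mitochondrially encoded genes (median 0.32), RNA polymerase II and general factors (0.12) and nuclear-encoded oxidative phosphorylation (0.01, with a mean of -0.03) were also called higher than other genes with a preset correlation, and had adjusted p = 0.953 with an estimated correlation. The call of oxidative phosphorylation was lost without RT10 4-OHT 2, vehicle 1 or vehicle 2, and that of general factors without RT10 4-OHT 2. None of the 10 calls in RT10 held with an estimated correlation on the spike-in scale. Their unadjusted camera p there ran from 0.0369 (integrated stress response) to 0.675 (oxidative phosphorylation), at estimated correlations of 0.318 to 0.858. The mitochondrial share was 0.924% to 1.23% in the 3 vehicle libraries and 1.56% to 1.85% in the 2 4-OHT libraries. Lists of naive and core pluripotency, p53 targets, SAGA subunits and heat shock were called in neither line.

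The responses of the lines were compared over genes, and no library belongs to both comparisons. Vehicle libraries of equal replicate number correlated between the lines, so the comparisons may still share a batch. On the spike-in scale, of the genes that fell, 80 were shared, where independent lists of these sizes share 2.59. Of those that rose 10 were shared, against 0.110. With TMM factors 305 that fell and 214 that rose were shared, against 26.7 and 13.9. On both scales more genes were shared in each direction than by independent lists. In proportion, shared lower genes outnumbered shared higher ones by much less with TMM factors. No gene was called in opposite directions. Of the 202 genes called in RT7, 193 had the same sign in RT10, and of the 365 called in RT10, 359 had the same sign in RT7. Across 12933 genes with a mean of at least 50 counts, Pearson's r of the log2 fold changes was 0.69 and Spearman's rho 0.69, across genes that are not independent replicates.

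**Figure D3:**
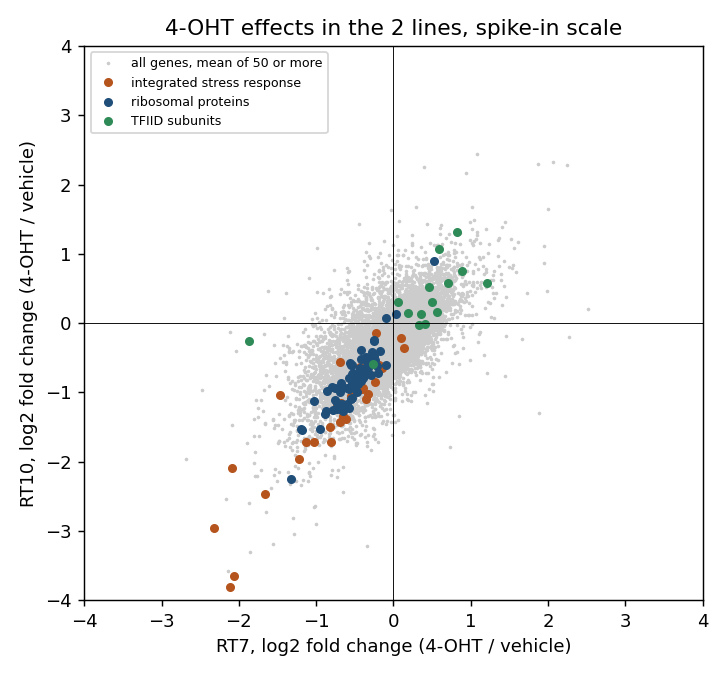
Log2 fold change after 4-OHT in RT7 (horizontal) and RT10 (vertical) on the spike-in scale, for genes with a mean of 50 or more scaled counts in grey; 1 gene lies outside the axes. Integrated stress response and ribosomal protein genes lie mostly at negative values in both lines, with medians of -0.65 and -0.49 in RT7 and of -1.09 and -0.79 in RT10, and TFIID genes mostly at positive values.

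A test of the difference between the effects called 3 genes, with 341 at an unadjusted p under 0.05, and each of the 3 had a lower effect in RT10. The direction depended on the design and the scale. With TMM factors 2 genes were called, 1 higher and 1 lower in RT10. A block on replicate number, which may join unmatched RT10 libraries, called 9 on the spike-in scale, 3 higher and 6 lower. With TMM factors that block called 196, 128 higher and 68 lower. Ccnb1ip1 had a difference of -2.87 ± 0.48 on the log2 scale (SE; edgeR adjusted p = 5.24e-05). With vehicle it had 60.4 ± 12.1 scaled counts in RT7 and 4069 ± 1512 in RT10 (mean ± SD, n = 3 and 3). Its difference of effects thus cannot be told apart from the unlike starting levels of the lines. Crxos (-3.18 ± 0.64) and S100a13 (-2.53 ± 0.52) were outside the naming rule and are named after their values were seen. With TMM factors Ccnb1ip1 passed (edgeR adjusted p = 7.95e-04), while Crxos (0.795) and S100a13 (0.841) did not, and DESeq2 with spike-in factors called 1 gene. Taf7 had a difference of 1.60 ± 0.44 (edgeR adjusted p = 0.441), and 3.81e-04 with TMM factors. Fgf1 (2.09 ± 0.70), Btla (1.83 ± 0.62), Mirt1 (1.75 ± 0.62) and Col6a5 (1.87 ± 0.68) had the next smallest p among genes with a higher effect in RT10 and did not pass. Without RT7 vehicle 2 the count was 46, without RT7 4-OHT 3 it was 9, and without RT7 vehicle 3 or RT10 vehicle 2 it was 1.

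The vehicle libraries of the lines, which received no 4-OHT, were also compared. Olig2, a transcription factor gene of the neural lineage, had 216 ± 58.2 spike-in-scaled counts in RT7 (mean ± SD, n = 3) and a single raw count in RT10, so no fold is given. The genes AA467197 (-4.85 ± 0.40), Gt(ROSA)26Sor, the transcript of the locus that carries Cre (-4.22 ± 0.33), Tmem154 (-4.13 ± 0.52) and the imprinted H19 (-3.55 ± 0.41) were lower in RT10. Ctse (7.10 ± 0.60), Zbbx (6.70 ± 0.49), Ccnb1ip1 (6.08 ± 0.37), Wdr64 (5.12 ± 0.47) and Zfp352 (5.08 ± 0.55) were higher in RT10 (log2 difference ± SE). With TMM factors the log2 differences of the lower genes were -4.14, -3.53, -3.45 and -2.84, and those of the higher genes 7.64, 7.34, 6.68, 5.75 and 5.57, in the same order. Of the 19 tested genes of the two-cell-like state, 16 were higher in RT10 and 1 was lower, with a median log2 difference of 3.24 (adjusted p = 0.323 with an estimated correlation). With TMM factors 16 were higher and 0 lower, with a median of 3.81 (adjusted p = 0.922 with an estimated correlation). On the spike-in scale 9281 of 18674 genes differed, 958 higher and 8323 lower in RT10, with a median of -0.72. With TMM factors 4852 differed, 2497 higher and 2355 lower, and 51.5% of calls were higher against 10.3%. The ratio of mouse to Drosophila counts was 3.49 in RT7 and 1.75 in RT10 (exact permutation p = 0.1, the smallest possible). In the Drosophila counts themselves 4638 of 8520 genes differed between these vehicle libraries, while 0 differed between treatments in RT7 and 0 in RT10 (edgeR, with 147 and 91 at an unadjusted p under 0.05). The spike-in scale between lines therefore rests on Drosophila RNA whose composition was not the same in both. Without RT7 vehicle 2 the count was 5149 and without RT10 vehicle 1 it was 4902.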

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

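The tests of the spike-in error, of carried-over RNA and of 4-OHT or Cre were chosen after the results were seen, as were the list test of the difference and the splits with TMM factors. Groups of 2 or 3 libraries are too small for a test of single outlying samples.

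The effects differed between the lines for Ccnb1ip1 (RT10 minus RT7, log2, -2.87), Crxos (-3.18) and S100a13 (-2.53) on the spike-in scale. Ccnb1ip1 started from a mean of 60.4 scaled counts in RT7 vehicle libraries and 4069 in RT10 vehicle libraries. With TMM factors the calls of Crxos (edgeR adjusted p = 0.795) and S100a13 (0.841) were lost. The same contrast tested on gene lists called the two-cell-like state (median difference 0.20), the integrated stress response (-0.55), S phase and E2F targets (-0.39), formative and primed pluripotency (0.19), replication-dependent histones (-0.40), imprinted genes (-0.28), ribosome biogenesis (-0.34), ribosomal proteins (-0.32) and the unfolded protein response (-0.42). The median over all genes was -0.24, and none of these lists held with an estimated correlation (adjusted p = 0.977). With TMM factors and the preset correlation, the calls of histones (adjusted p = 0.222), imprinted genes (0.278), ribosome biogenesis (0.220), ribosomal proteins (0.335) and the unfolded protein response (0.111) were lost. TFIID subunits were called there (adjusted p = 0.00404, and 0.322 with an estimated correlation). That list holds Taf7, which is deleted in RT7 only and was its 1 member called with TMM factors (difference 1.86). The list median was 0.12, against 0.03 over all genes, and the list without Taf7 was not tested.

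The first pattern is the excess of lower values on the spike-in scale. Between the vehicle libraries of the lines 4638 Drosophila genes differed, or 54.4% of those tested, against 0 between treatments within either line. The first component of the Drosophila profile held 74.3% of its variance and separated all RT7 from all RT10 libraries. A different spike-in preparation or separate handling for each line may therefore account for part of the lower level in RT10 vehicle cells, and a true difference in labelled RNA cannot be separated from it. Within RT10, the ratio differed between treatments by -1.01 SD of the vehicle libraries, so an error of the spike-in scale and less labelled RNA after 4-OHT cannot be told apart with 3 and 2 libraries.

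Other splits of the 6 RT7 libraries bear on the same scale. Of the 10 splits into 3 and 3, 3 gave at least the 202 genes of the real split, and the highest other gave 5815; 10 splits are too few for a share under 0.05. That split set RT7 vehicle 2, 4-OHT 1 and 4-OHT 2, which have the highest ratios of mouse to Drosophila counts, against the rest, which points to a structure of the samples. The splits that, like the real one, part all 3 pairs of equal numbers gave 0, 7 and 2 genes. With TMM factors the real split gave 1283 genes and each other split 0. For gene lists, 4 of the 10 splits gave at least the 13 lists of the real split, and the highest other gave 17. For gene lists with TMM factors the real split gave 13 and the highest other 19. For the vehicle comparison 1 of 10 splits, the real one, gave 9281 genes or more, and the highest other gave 67.

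The second pattern is the lower level of integrated stress response and ribosomal protein genes in both lines, a call lost with an estimated correlation (adjusted p = 0.900 in RT7 and 0.953 in RT10). A trend with gene span, transcript length and GC content was taken out on the TMM scale. The medians went from -0.67 and -0.54 to -0.47 and -0.47 in RT7 (with the replicate block). In RT10 they went from -0.85 and -0.54 to -0.87 and -0.63. The trend thus took part of the fall in RT7 and left most of each median, which argues against it as the whole cause. All lay below 10000 random lists of the same sizes. Those lists drew genes singly, while the genes of these lists vary together, so that rank overstates the evidence. Less carry-over of unlabelled mature RNA remains open for the ribosomal protein genes, because mitochondrially encoded genes were higher (median 0.48 in RT7 and 0.58 in RT10, TMM scale) while the share of counts overlapping ribosomal RNA was lower (15.6% and 12.1% in RT7, 11.4% and 9.50% in RT10, vehicle and 4-OHT). An effect of 4-OHT or of active Cre itself also remains open: 80 genes fell in both lines, and no treated cells without floxed Taf alleles were analysed here. Loss of TFIID function, which the design names, is not tested apart from these.

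The third pattern is the higher level of TFIID subunit genes in both lines, which in RT7 was lost with an estimated correlation (adjusted p = 0.900, and 0.136 with TMM factors) and in RT10 held with TMM factors only (adjusted p = 0.953, and 0.0259 with TMM factors). When the trend with span, length and GC content was taken out on the TMM scale, their median went from 0.42 to 0.52 in RT7 (with the replicate block). In RT10 it went from 0.55 to 0.50. The medians were thus largely kept, which argues against that trend as the whole cause. They lay above at least 99.95% of 10000 random lists, a rank with the same limit of singly drawn genes. The loss of a TFIID subunit, which the design names, and an effect of 4-OHT or Cre both remain open, and no test here sets them apart.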

How the results depend on the processing

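The leave-outs with TMM factors, the block in RT7 alone and the estimated correlation with TMM factors were chosen after seeing the data. The change of Taf7 in RT7 stayed past the threshold in all 25 alternatives (log2 fold change -2.05 to -1.56), Taf7 in RT10 and Taf10 in both lines stayed short of it, and the ratio of mouse to Drosophila counts moved by less than its spread in RT7 (-0.08 to 0.20) and RT10 (-0.41 to -0.14). Counts of genes moved most; the cause was not tested except where fewer libraries or a fold threshold were used. With TMM factors of the mouse counts the counts were 1283 (RT7), 1186 (RT10) and 4852 (vehicle lines). With DESeq2 size factors of the mouse counts they were 1282, 1148 and 4611, and with only the groups compared 79 in RT7 and 1170 in RT10. DESeq2 gave 126 in RT7 and 1 for the difference with spike-in factors, and 2082 (RT7), 1934 (RT10), 20 (difference) and 4775 (vehicle lines) with its own. A test against a 1.5-fold change gave 27 in RT7, 94 in RT10 and 2702 between vehicle lines. The replicate block gave 447 in RT7, 593 in RT10 and 9 for the difference; with TMM factors the blocked counts were 2671 (RT7), 2576 (RT10), 196 (difference) and 5602 (vehicle lines), and the block in RT7 alone gave 643. The block ended no call of a named gene or list in RT7. Numbers were taken as pairs in RT7 only. Elsewhere the block is a shared number, and in RT10 it may join unmatched libraries. Leaving out 1 library gave 33 to 301 genes in RT7, 14 to 475 in RT10, 1 to 46 for the difference, 4902 to 10577 between vehicle lines, and 13 to 17 lists in RT7 and 8 to 10 in RT10. With TMM factors, leaving out RT7 vehicle 1, 2 or 3 gave 678, 719 or 744 genes, RT7 4-OHT 1, 2 or 3 gave 455, 1246 or 525, RT10 vehicle 1, 2 or 3 gave 613, 635 or 1190, and RT10 4-OHT 1 or 2 gave 519 or 55; where 1 RT10 4-OHT library is left, it is assumed to vary like the other groups. Gene lists called fell to 0 in RT7 and 0 in RT10 with an estimated correlation and with fry, and to 0 and 1 with an estimated correlation and TMM factors. The direction of nuclear-encoded oxidative phosphorylation in RT10 (median 0.0071) was opposite with fry, which does not compare a list with other genes. Of the named genes' values under alternatives, 5982 kept their call and direction, 646 newly passed and 356 no longer passed; of the lists', 428 kept it and 116 lost it. Simulated changes of 1.5-fold, drawn with the spread of the spike-in scale, were recovered in 0% (RT7) to 4.48% (vehicle lines) of genes, a limit of that scale; the smaller spread on the TMM scale was not simulated.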

Other observations

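The tests of gene families were chosen after the results were seen; the test of the neighbours of Taf7 was set before its values were looked at. Host genes of small nucleolar RNAs (Snhg genes, Gas5 and Dancr), many of which share the promoter type of ribosomal protein genes, lay lower in both lines on the TMM scale. In RT7, with the replicate block, 7 of 15 fell and 0 rose, with a median log2 fold change of -0.72 (camera p = 3.52e-08, p = 0.0815 with an estimated correlation). In RT10, 6 fell and 0 rose, with a median of -0.78 (camera p = 1.07e-07, p = 0.0681 with an estimated correlation). As a hypothesis, they may move with the ribosomal protein genes, though the calls do not hold with an estimated correlation.

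Platr transcripts, noncoding RNAs associated with pluripotency, were tested because Platr3 fell in RT7 (log2 fold change -2.17 ± 0.33, SE). Platr3 also fell in RT10 (-2.54 ± 0.39, edgeR adjusted p = 7.05e-08). On the TMM scale, with the replicate block, of 27 tested genes 7 fell and 2 rose in RT7, with a median of -0.32 (camera p = 0.000215, p = 0.0959 with an estimated correlation). Without Platr3, which prompted the test, 6 of 26 fell and 2 rose, with a median of -0.32 (camera p = 0.00393, p = 0.160 with an estimated correlation). In RT10 the median was 0.072 (1 of the 27 rose and 4 fell), so the family as a whole was not lower there; the difference of the family between the lines was not tested.

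Gm37446 (ENSMUSG00000103985, annotated as antisense, mm10 chromosome 18, 37433412 to 37437547) had 0 counts in the 3 RT7 vehicle libraries and 97.7 ± 32.1 scaled counts (mean ± SD) in the 3 RT7 4-OHT libraries; it was chosen after its values were seen, and whether counting used strand is not known. It lies on the chromosome of Taf7, and in the 5 RT10 libraries it had at most 1.02 scaled counts. An altered neighbourhood of the floxed gene is a possible explanation. In RT7 0% of the 30 other tested genes within 1 Mb of Taf7 were called, against 1.07% of other genes (Fisher's exact p = 1). On the TMM scale 3 of the 30 were called, or 10% against 6.86% of other genes (Fisher's exact p = 0.458). So few calls were due among 30 genes that the test cannot show an unchanged neighbourhood. Their median log2 fold change was 0.13 on the spike-in scale and 0.08 with TMM factors. The explanation remains open, and what makes Gm37446 appear was not found.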
